A study of Homo sapiens with 12 samples.

How the data were processed

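RNA of the HUES7 cultures was extracted with TriReagent, checked on a Bioanalyzer, amplified with biotin labelling and hybridized to HT12v4 BeadChips, per the labels. The deposited intensities were read out with GenomeStudio 1.7.0, per the submitters' processing notes. The non-normalized intensity table was deposited as probe values on a linear scale without background subtraction or scaling between arrays. The deposited detection p-values stood to the right of each intensity column under the header Detection Pval and moved in steps of 1 in 770. They were taken to be those of GenomeStudio against the negative control probes of each array, which the headers do not state. A second deposited table held intensity values that had been quantile normalized on a linear scale without background subtraction, as judged from its values. Its column medians lay between 98.02 and 98.06, and each column had a rank correlation of 1.0000 with the non-normalized column of the same array. The slide of each array was not given.

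The non-normalized table, with 47323 probes, was used. The limma function neqc inferred the negative controls from the detection p-values, corrected the background, added an offset of 16, normalized by quantiles and took log2. A probe was kept if its detection p was under 0.01 on at least 3 arrays, which held for 20041 probes. Of all probes, 30113 listed 1 gene, 8 several and 17202 none. Of the kept probes, 15748 listed 1 gene, and the brightest was taken for each gene, which gave 11912 genes. The other 4293 kept probes were not tied to a gene. Among them 1493, 1217, 224 and 1319 changed in the 4 comparisons, taken in the order of the report. A further 92 probes were only in the non-normalized table, and 2 of their 1104 values (0.181%) were detected.

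One limma model with a mean for each stage was fitted to all 12 arrays, which left 8 residual degrees of freedom and 7.15 prior degrees of freedom. P-values came from the moderated statistics of limma, were adjusted by Benjamini-Hochberg over all genes, and were called under 0.05. Nothing in the labels says that replicates were separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. Gene lists were tested with camera at its preset correlation of 0.01 and again with an estimated one. Of 36 fixed lists, 11 of which hold markers of cell types, 33 had at least 4 measured genes and were tested. A call within a list was also made with p-values adjusted over that list alone. A fold from a group in which no array detected the probe was computed against the detection floor and written as at least. The same was done where 1 or 2 arrays detected the probe and the group mean lay under that floor. The number of arrays limits the precision of every value.

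The comparisons, tests, gene lists, thresholds, most alternatives and the rule for named genes were fixed before the data were examined. For each comparison the rule took the 6 largest rises and 6 largest falls among called genes that were detected on all 3 arrays of the higher group and did not overlap between groups. It left out XIST, Y-linked genes and unnamed open reading frames. It added up to 4 called members of each list with the largest changes, and 17 genes in every comparison. Of these, 1 is not reported here, and the others were GNRH1, KISS1, KISS1R, FGFR1, FGF8, TAC3, TACR3, NHLH2, ISL1, DLX5, POU5F1, NANOG, SOX2, PAX6, TUBB3 and MKI67. The text names fewer list members than the rule allows, and names members that did not pass only where a count is explained. Genes of the families in the last part were chosen after their values were seen.

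The model fit, the list test and the length correction were tested on simulated log2 values, with 200 changed genes of 11912. Background correction, scaling between arrays, the detection filter and the choice of probe were not simulated. The share of changed genes was smaller than the 16.2% to 52.8% called in the real comparisons. Between 61% and 79% of changes of 1 log2 and between 98% and 100% of changes of 2 log2 were recovered, with 1.84% to 6.4% false calls. These rates describe the simulated data and were not measured on the real arrays. On the real arrays, the standard deviation of the difference between arrays of the same stage was 0.471 to 0.686 log2 for GnRH-EC 21. It was 0.241 to 0.4 log2 for the other stages. The simulated rates may therefore not carry over to the comparisons that use the GnRH-EC 21 arrays. In a simulated length trend, 3562 false calls fell to 0 once the trend was removed. The alternatives changed the background correction, the offset, the scaling between arrays, the detection filter, the choice of probe, the table, the arrays in the fit, a block for the replicate number, the variance prior and the threshold, or left out each array in turn. R 4.3.3 and limma 3.58.1 were used.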

Results

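The data set holds 12 Illumina HT12v4 BeadChip arrays, each of which measured the messenger RNA of a whole culture with probes for most human genes. HUES7, a human embryonic stem cell line, was sampled at 4 stages with 3 arrays each. The stages were the undifferentiated stem cells at passage 41 (ESC), neural progenitor cells at passage 9 (NPC), and cells kept with FGF8 for 21 days or 35 days, which the labels call GnRH-expressing cells (GnRH-EC 21 and GnRH-EC 35). Gonadotropin-releasing hormone (GnRH) is the peptide with which a small group of hypothalamic neurons drives the reproductive axis. Between 14743 and 18897 probes were detected per array, and the mean deposited intensity ran from 174 to 335. Arrays of the same stage correlated across genes at 0.982 to 0.991 for ESC, 0.989 to 0.992 for NPC and 0.98 to 0.992 for GnRH-EC 35. The GnRH-EC 21 arrays were less alike, at 0.94 to 0.972. The expression of 9585 of the 11912 genes tested (80.5%) differed among the 4 stages (limma F test, Benjamini-Hochberg adjusted p under 0.05). The first principal component carried 61.3% of the variance and set ESC apart, and the second carried 21.9%. On the second the GnRH-EC 21 arrays lay at 75.3, 56.8 and 20.8, and every other array lay under 10. On that component GnRH-EC 21 replicate 3 lay between the rest of its group and the other stages. It correlated at 0.949 to 0.951 with the NPC arrays and at 0.936 to 0.954 with the GnRH-EC 35 arrays. Its correlation was 0.94 with GnRH-EC 21 replicate 1 and 0.968 with replicate 2. Replicate 1 had the fewest probes detected, 14743.

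The NPC and ESC arrays were compared to show what changed when noggin, followed by FGF2 and EGF, turned stem cells into neural progenitors. Genes that hold stem cells in the pluripotent state fell. POU5F1, which encodes OCT4, fell at least 79.9-fold (adjusted p = 2.32e-13) and was not detected on any NPC array. NANOG, a partner of OCT4, fell at least 18.8-fold (adjusted p = 5.75e-13). L1TD1, an RNA-binding protein of stem cells, fell at least 106-fold, and the E-cadherin gene CDH1 fell at least 47.3-fold. EPCAM, an adhesion molecule of stem cells and epithelia, fell by 6.68 ± 0.18 on the log2 scale (adjusted p = 3.05e-13). All errors are standard errors of the log2 change from limma, with n = 3 arrays per group, and folds written as at least were computed against the detection floor. Of 23 measured pluripotency genes, 22 fell and 0 rose, with 22 fallen when adjusted over the list alone (median log2 change −2.67; camera adjusted p = 5.59e-15). SOX2, which both stem cells and neural progenitors use, did not pass the threshold (0.12 ± 0.22; adjusted p = 0.675).

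Genes of neural progenitors rose in their place. The Notch effector HES5 rose at least 213-fold (adjusted p = 6.45e-15), and the neural transcription factors POU3F2, NR2F1 and PAX6 rose at least 83.6-fold, 34.5-fold and 15.4-fold. FABP7, a fatty acid carrier of radial glia, rose by 5.04 ± 0.15 log2, or 32.8-fold. Of 19 measured neural progenitor genes, 15 rose and 0 fell, with 16 risen when adjusted over the list alone (camera adjusted p = 2.01e-09). The proneural factor NEUROG2 rose 33.6-fold (5.07 ± 0.18), INSM1 rose 10.2-fold, and 8 of 12 measured proneural genes rose with 0 falling (adjusted p = 8.59e-05). Genes of young neurons were already higher in NPC. STMN2, a microtubule regulator of growing axons, rose 66.5-fold (6.06 ± 0.20), the migration gene DCX rose 21.9-fold (4.45 ± 0.40), and the neuronal tubulin gene TUBB3 rose 4.59-fold (2.20 ± 0.18). Across the pan-neuronal list 12 of 20 genes rose and 3 fell (camera adjusted p = 0.000239), a call that was lost with an estimated correlation (adjusted p = 0.0817).

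Among the largest single changes, MIR124-2HG, the host transcript of a neuronal microRNA, rose at least 53.4-fold and the transcription factor gene ZFHX3 rose at least 47.2-fold. The metallothionein gene MT1G fell by 6.39 ± 0.20 log2, 83.8-fold, but it has near-identical copies and is uncertain. Patterning genes moved both ways. OTX1 rose at least 8.15-fold and LHX2 at least 3.50-fold, whereas ZIC2 fell 17.6-fold and OTX2 fell 4.75-fold, so that 3 of 11 anterior forebrain genes rose and 4 fell (adjusted p = 0.873; the median of the list was 0.14 and its mean −0.12). The enzymes of cholesterol synthesis rose almost without exception, with 11 of 12 risen and 0 fallen, among them HMGCS1 (8.66-fold, 3.11 ± 0.28), IDI1 (7.67-fold) and MSMO1 (6.73-fold), at a camera adjusted p of 3.99e-06. All 8 measured epithelial genes fell (adjusted p = 3.99e-06, or 0.0599 with an estimated correlation). The migration gene CXCR4 rose at least 14.2-fold and the adhesion gene CNTN2 rose 15.8-fold, in a list in which 11 of 22 rose and 2 fell (adjusted p = 0.00545, or 0.0508 with an estimated correlation). The smooth muscle actin gene ACTA2 rose 43.9-fold (5.46 ± 0.20), and 7 of 12 mesenchymal genes rose and 3 fell (adjusted p = 0.0285, or 0.227 with an estimated correlation).

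Neurosecretory genes moved both ways, with 5 of 15 risen and 5 fallen (adjusted p = 0.706). SNAP25 rose at least 4.79-fold, and the granule genes CHGA and SCG5 fell 17.9-fold and 16.7-fold. The peptide gene GAL fell at least 43.9-fold. FLRT3, a partner of FGF receptors, rose at least 17.4-fold and FGFR3 rose 8.28-fold, while the FGF feedback genes SPRY4 and ETV4 fell 8.63-fold and 10.4-fold. Over the FGF feedback list, 10 of 19 genes rose and 5 fell (adjusted p = 0.451). The proliferation gene MKI67 rose by 1.29 ± 0.22 log2, with 7 of 29 cell cycle genes risen and 7 fallen (adjusted p = 0.953). Over all 11912 genes, 3228 rose and 3066 fell, of which 1552 and 1521 changed at least 2-fold. Of the 33 gene lists tested, 13 passed, 9 upward and 4 downward, and 4 of these held with an estimated correlation.

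**Figure D1:**
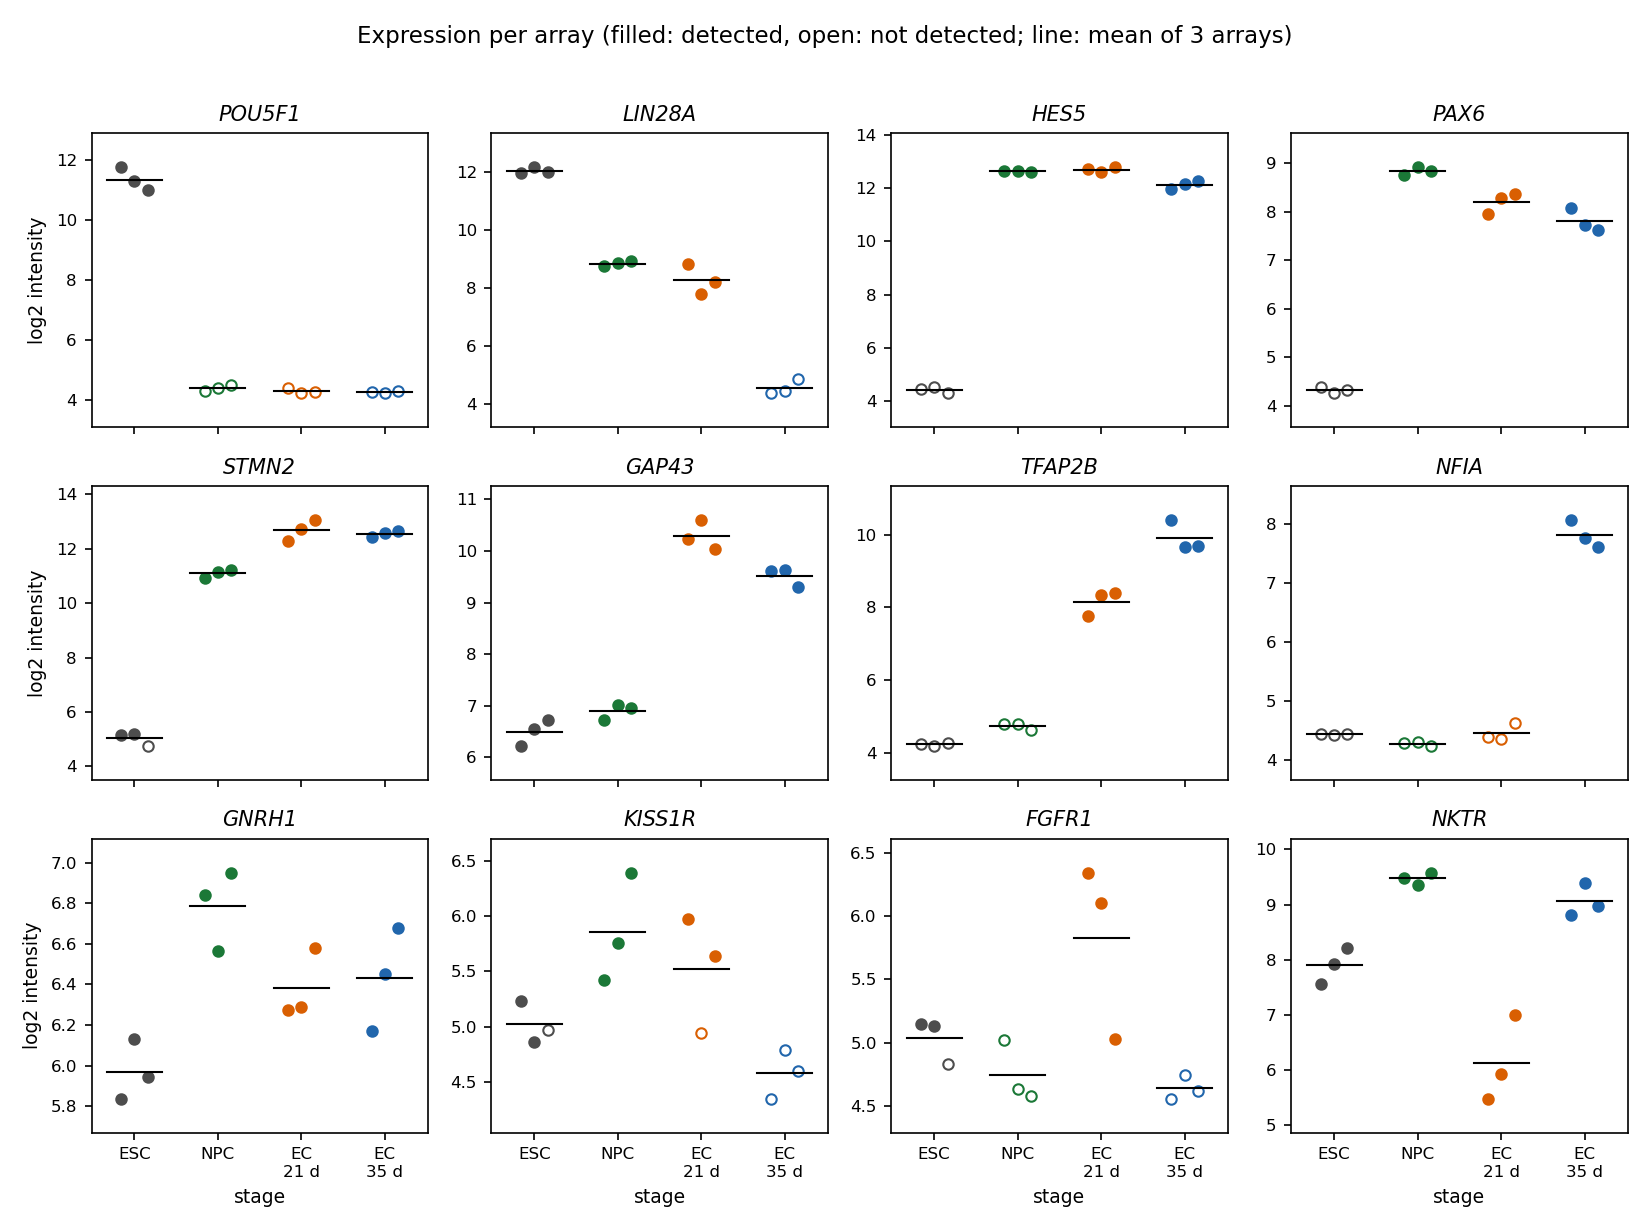
Log2 intensity of 12 genes on each of the 12 arrays (each point is 1 array, the line is the mean of 3 arrays, open points are arrays on which the probe was not detected, and the vertical axes differ between panels). POU5F1 was detected only in ESC, NFIA only at 35 days, and GNRH1 on all 12 arrays with its highest mean, 6.79, in NPC.

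The comparison of GnRH-EC 21 against NPC addressed what changed over 21 days with FGF8. No culture was kept as long without FGF8, so neither this comparison nor that at 35 days separates FGF8 from time in culture or from the end of FGF2 and EGF. Pan-neuronal genes rose. MAPT, which encodes the axonal protein tau, rose 13.7-fold (3.78 ± 0.17 log2; limma adjusted p = 2.51e-09), and GAP43, a protein of growth cones, rose by 3.40 ± 0.19 log2 (adjusted p = 1.21e-08). STMN4 rose by 2.74 ± 0.16 log2 and the neurofilament gene NEFL rose 4.82-fold. Of 20 measured pan-neuronal genes, 14 rose and 0 fell, and 16 rose when adjusted over the list alone (median log2 change 1.35; camera adjusted p = 1.38e-07, or 0.0862 with an estimated correlation). In TUBB3, GnRH-EC 21 against NPC gave a rise of 0.50 ± 0.18 log2 (adjusted p = 0.0326), a call that was lost when NPC replicate 1, 2 or 3 or GnRH-EC 21 replicate 1 was left out (adjusted p from 0.0572 to 0.0987, and from 0.00332 to 0.127 over all alternatives).

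Genes of synapses and of peptide secretion rose too. The vesicle genes SYP and SYN1 rose 4.57-fold and 4.46-fold, and SNAP25, part of the release machinery, rose 4.07-fold (2.03 ± 0.20). Of 20 measured synapse genes, 12 rose and 2 fell (adjusted p = 0.00419, or 0.185 with an estimated correlation). PCSK1N, an inhibitor of the convertases that cut prohormones, rose 6.54-fold, CADPS, which primes dense-core vesicles, rose 6.36-fold, and the granule gene SCG2 rose 4.24-fold. In that neurosecretory list 10 of 15 genes rose and 1 fell (adjusted p = 0.00102, or 0.185 with an estimated correlation). The peptide genes TAC1 and NPY rose at least 3.69-fold and at least 2.15-fold and NTS fell (adjusted p = 0.00222). Of 10 measured neuropeptide genes, 3 rose and 3 fell (adjusted p = 0.979, with a median of −0.21 log2 and a mean of 0.16). TH, the first enzyme of dopamine synthesis, rose by 1.38 ± 0.15 log2.

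Single genes of forebrain patterning also rose in GnRH-EC 21 against NPC. LHX2, a factor of the anterior forebrain, rose by 2.09 ± 0.15 log2 (4.26-fold), ZIC2 rose 2.79-fold and OTX2 rose 2.16-fold. Of 11 anterior forebrain patterning genes, 6 rose and 0 fell (adjusted p = 0.0457, or 0.185 with an estimated correlation), and this list did not pass without NPC replicate 3 (0.0591) or without GnRH-EC 21 replicate 3 (0.117), with a range of 0.0199 to 0.185 over all alternatives. The FGF feedback genes ETV5 and SPRY4 rose 2.36-fold and 2.11-fold, within a list in which 6 of 19 rose and 3 fell, or 8 and 3 when adjusted over the list alone (camera adjusted p = 0.222). TFAP2B, a factor of neural crest and of some hindbrain and retinal neurons, rose at least 8.75-fold. The largest rises were those of RPRM, a cell cycle inhibitor (4.13 ± 0.17, 17.5-fold), and of the membrane protein gene TMEFF2 (3.95 ± 0.15, 15.4-fold). RNA28SN5 also rose by 3.79 ± 0.48 log2, but it stands for multi-copy ribosomal RNA and is uncertain.

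Epithelial genes were among those that fell in GnRH-EC 21 against NPC. TM4SF1 fell at least 9.42-fold, TGM2, a transglutaminase, at least 7.81-fold, and the keratin genes KRT19 and KRT8 at least 7.66-fold and at least 5.28-fold. S100A10, an annexin partner, fell by 3.87 ± 0.26 log2 (14.7-fold). Of 8 measured epithelial genes, 5 fell and 0 rose (adjusted p = 0.0347, or 0.378 with an estimated correlation), a call that was also lost without GnRH-EC 21 replicate 3 (0.117), with cyclic loess (0.169) and with median centring (0.112), and ranged from 0.00888 to 0.378 over all alternatives. MKLN1 and NKTR fell by 3.36 ± 0.20 and 3.34 ± 0.30 log2. The mitotic genes CENPF and TOP2A fell 9.38-fold and 5.93-fold and MKI67 fell at least 2.66-fold. Over the cell cycle list 9 of 29 genes fell and 0 rose, without passing the list test (adjusted p = 0.0594), although it passed without GnRH-EC 21 replicate 1 (0.0201) or 2 (0.0337) and ranged from 0.000931 to 0.352 over all alternatives. LIN28B, an inhibitor of let-7 microRNA, fell by 2.20 ± 0.21 log2. The neural stem cell factor PAX6 fell by 0.64 ± 0.17 log2 (adjusted p = 0.00695). SOX2, GnRH-EC 21 against NPC, fell by 0.75 ± 0.22 log2 (adjusted p = 0.0127), and without GnRH-EC 21 replicate 1 it fell by 0.42 log2 (0.0308). That call was lost under 5 of 21 alternatives, over which the adjusted p ranged from 0.00266 to 0.105. A second, dimmer SOX2 probe overlapped between the groups. It read 9.74, 10.26 and 10.76 log2 in GnRH-EC 21 and 10.46, 10.52 and 10.53 in NPC, so the fall rests on 1 probe.

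In all, 2617 genes rose and 2525 fell between NPC and GnRH-EC 21, of which 598 and 1232 changed at least 2-fold. The split depended on the scaling: with each array centred on its median in place of quantile normalization, 3315 genes rose and 2073 fell (61.5% risen against 50.9%), and the median of all genes was 0.246 log2 against 0.0908. With cyclic loess 2088 rose and 2674 fell (43.8% risen). With only the arrays compared in the fit, 3815 genes passed. With array weights 3084 genes passed, and with GnRH-EC 21 replicate 3 as the only array of its stage 2121 passed. Of 33 lists 6 passed, 5 upward and 1 downward. With camera's estimated correlation 0 held, and 5 had an unadjusted p under 0.05.

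The comparison of GnRH-EC 35 against NPC addressed what changed over the whole 35 days. Pan-neuronal, synapse and neurosecretory genes rose as lists. STMN4 rose by 2.64 ± 0.16 log2 (limma adjusted p = 2.59e-08), GAP43 rose 6.13-fold, NEFL 5.67-fold and MAPT 4.66-fold. Of 20 measured pan-neuronal genes, 15 rose and 0 fell, with 17 risen when adjusted over the list alone (median 1.39; camera adjusted p = 2.57e-15, and 0.00509 with an estimated correlation). The glutamate receptor gene GRIA2 rose 5.30-fold and the calcium sensor genes SYT4 and SYT1 rose 4.51-fold and 3.25-fold, and 12 of 20 synapse genes rose with 0 falling (adjusted p = 2.95e-08). SCG2 rose 5.14-fold and CPE, which trims peptide hormones, rose 4.47-fold, in a neurosecretory list in which 8 of 15 rose and 1 fell (adjusted p = 7.57e-05). The somatostatin gene SST rose at least 7.19-fold (adjusted p = 2.45e-07), but of 10 neuropeptide genes 2 rose and 2 fell (adjusted p = 0.926, with a median of −0.25 log2 and a mean of 0.23). Of 12 neuronal ion channel genes 4 rose and 0 fell (adjusted p = 0.0471, or 0.256 with an estimated correlation), a call also lost without NPC replicate 1 (0.0769) or GnRH-EC 35 replicate 2 (0.0736) or 3 (0.0526), with a range of 0.00459 to 0.275.

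Single transmitter genes and proneural genes rose with them. SLC17A6, the vesicular glutamate transporter, rose 2.92-fold, GAD1, which makes GABA, rose 2.75-fold and TH rose 2.33-fold. Only 4 of the 16 listed transmitter genes were measured, namely these and DDC, which was detected on 1 GnRH-EC 35 array. Among proneural genes MYT1L and MYT1 rose at least 3.84-fold and 3.35-fold, and 6 of 12 rose with 0 falling, or 9 and 1 when adjusted over the list alone (camera adjusted p = 1.7e-05). The BMP target genes ID3, ID2 and ID1 rose by 2.40 ± 0.23, 2.21 ± 0.17 and 2.03 ± 0.23 log2, with 5 of 9 measured targets risen and 0 fallen (adjusted p = 9.65e-05). The netrin receptor gene DCC rose at least 2.43-fold, its ligand gene NTN1 3.18-fold and CXCR4 3.14-fold, in a migration list with 10 of 22 risen and 3 fallen (adjusted p = 0.00124). Cholesterol synthesis genes rose, 7 of 12 with 1 falling, or 10 and 1 when adjusted over the list alone, among them MVD (2.06-fold) and LSS (camera adjusted p = 0.000144).

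The largest rises at 35 days were those of MIR9-1HG, host of a neuronal microRNA (at least 49.3-fold), TFAP2B (at least 29.7-fold), the retinoic acid hydroxylase gene CYP26A1 (at least 17.2-fold) and PI15 (4.35 ± 0.17, 20.4-fold). NFIX, a nuclear factor of late progenitors and glia, was not detected in NPC and rose (adjusted p = 1.5e-09), and the glial regulator SOX9 rose by 2.89 ± 0.23 log2. The astrocyte transporter gene SLC1A2 rose 3.36-fold, but 2 of 8 astrocyte markers rose and 1 fell (adjusted p = 0.926).

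Cell cycle genes fell as a list, and single genes outside it fell too. LIN28A, an RNA-binding protein that keeps cells immature, fell at least 13.9-fold (adjusted p = 3.9e-09) and was detected on no GnRH-EC 35 array. Of 29 measured cell cycle genes, 27 fell and 0 rose, 28 when adjusted over the list alone (median −1.05; camera adjusted p = 6.58e-17, and 0.00218 with an estimated correlation). CDC20 fell by 1.44 ± 0.21 log2, BUB1 by 1.42 ± 0.20, AURKA by 1.41 ± 0.15, and MKI67 by 1.23 ± 0.22. PAX6 fell by 1.03 ± 0.17 log2 and OTX1 3.35-fold. TM4SF1 fell at least 10.3-fold, TGM2 at least 8.51-fold, KRT19 at least 8.35-fold and S100A10 by 3.73 ± 0.26 log2. Of 8 epithelial genes 4 fell and 0 rose (adjusted p = 0.000228, or 0.0939 with an estimated correlation). The natriuretic peptide gene NPPB fell at least 13.8-fold.

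In all, 858 genes rose and 1069 fell in GnRH-EC 35 against NPC, of which 402 and 388 changed at least 2-fold. With only these 6 arrays in the fit 3035 genes passed, and with array weights 4337. Of 33 lists 15 passed, 11 upward and 4 downward, and 9 held with an estimated correlation. Among those that did not hold, the neural progenitor list (5 of 19 risen, 3 fallen; adjusted p = 0.0465, or 0.282 with an estimated correlation) also failed without NPC replicate 3 (0.061) or GnRH-EC 35 replicate 2 (0.0514) or 3 (0.0584), and ranged from 0.0336 to 0.282 over all alternatives. The pluripotency list (2 of 23 risen, 7 fallen; adjusted p = 0.0329, or 0.112 with an estimated correlation) failed without NPC replicate 3 (0.0643), with cyclic loess (0.354) and with median centring (0.557), its range being 0.00734 to 0.557.

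**Figure D2:**
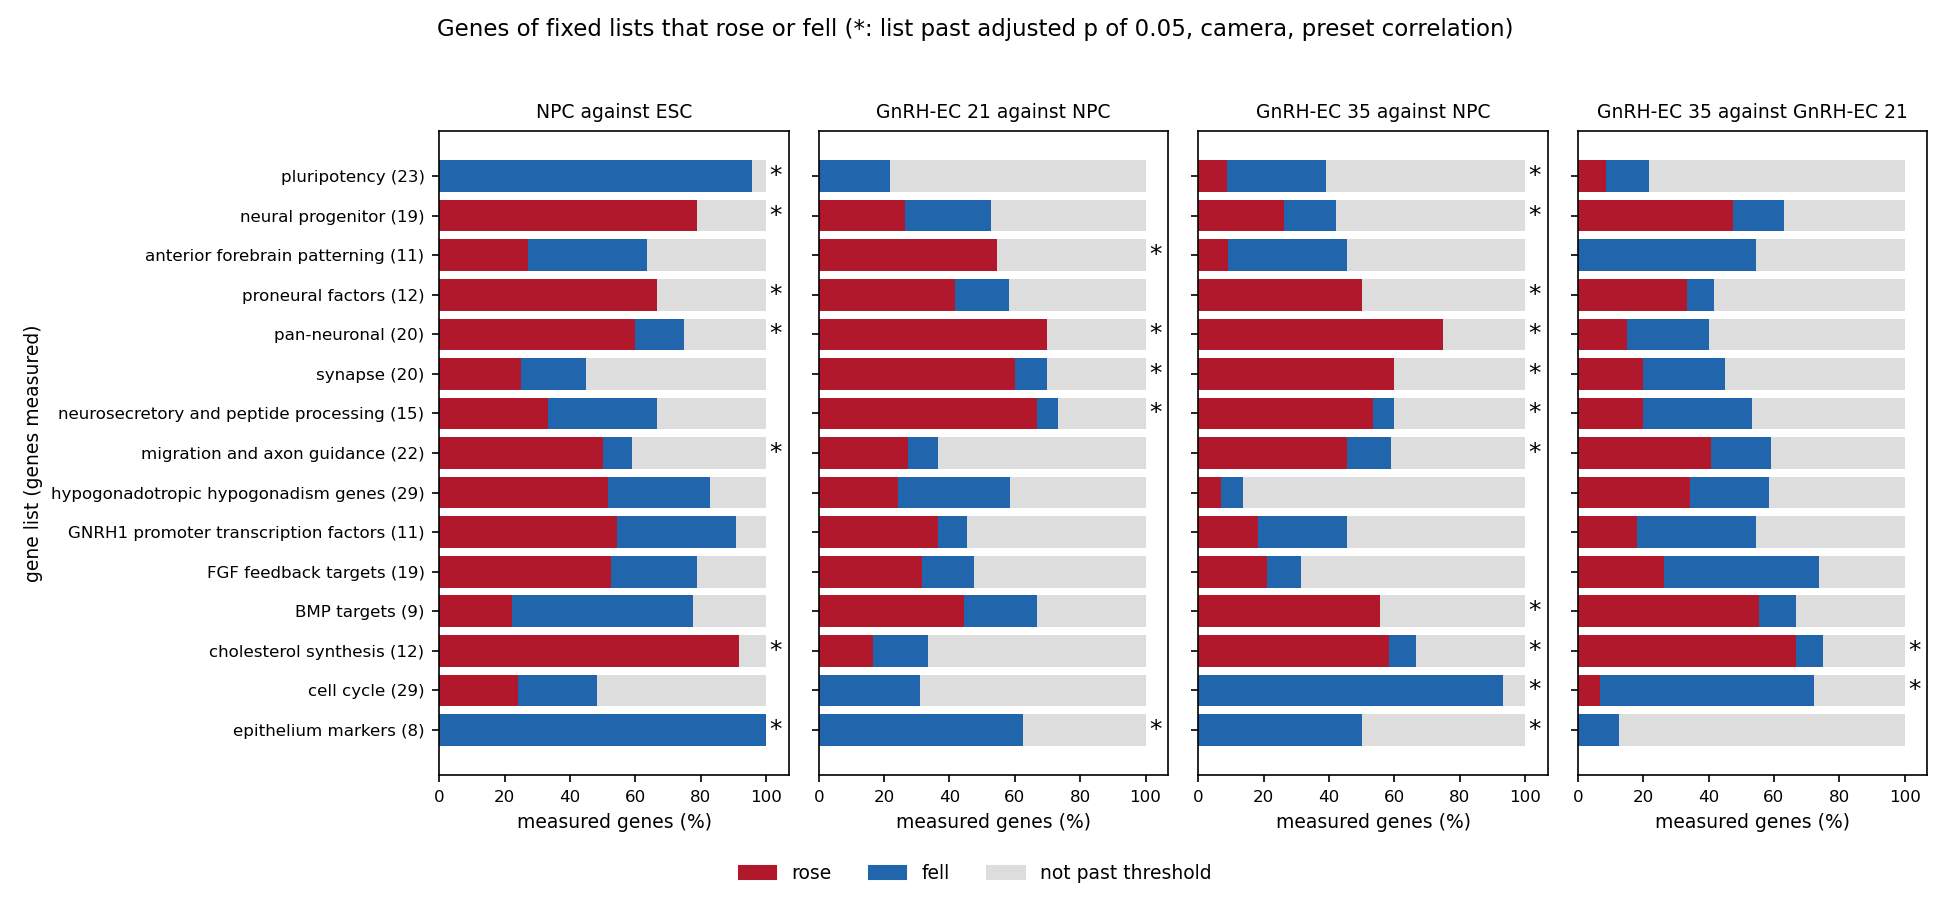
Share of the measured genes of 15 fixed gene lists that rose (red), fell (blue) or did not pass the threshold (grey) in each of the 4 comparisons, with an asterisk where the list passed camera's test with its preset correlation. The cell cycle list was at 0 risen and 27 fallen of 29 at 35 days against NPC, and the pan-neuronal list at 14 and 15 risen of 20 at 21 and 35 days.

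The comparison of GnRH-EC 35 against GnRH-EC 21 showed what changed between the sampling days. NFIA, a nuclear factor that opens glial differentiation, was detected only at 35 days and rose at least 6.20-fold (limma adjusted p = 1.21e-08). ZBTB20, a transcription factor gene, rose at least 15.1-fold (adjusted p = 3.62e-08), CYP26A1 at least 15.5-fold and PI15 10.2-fold. SOX9 rose 3.03-fold and SLC1A2 at least 4.25-fold, and 5 of 8 astrocyte markers rose and 1 fell (adjusted p = 0.378). SST rose at least 6.48-fold (adjusted p = 9.84e-07), SYT1 5.62-fold and GRIA2 by 1.89 ± 0.19 log2, while SYN1 fell 2.02-fold. Their lists did not pass, with 4 of 20 synapse genes risen and 5 fallen (adjusted p = 0.786), 3 of 20 pan-neuronal genes risen and 5 fallen (0.781), and 2 of 10 neuropeptide genes risen and 2 fallen (0.993). ST18, a factor of new neurons, rose by 3.17 ± 0.25 log2. The BMP targets ID3 and ID1 rose 2.89-fold and 2.26-fold, within a list with 5 of 9 risen and 1 fallen (adjusted p = 0.0519). That list passed without GnRH-EC 21 replicate 1 (0.0225) or 2 (0.0387), or without GnRH-EC 35 replicate 1 (0.0351), and its adjusted p ranged from 0.0051 to 0.206 over all alternatives.

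Other genes fell in GnRH-EC 35 against GnRH-EC 21. LIN28A fell at least 9.37-fold and RPRM by 2.94 ± 0.17 log2. LHX2 fell by 2.62 ± 0.15 log2 (limma adjusted p = 3.62e-08), OTX1 4.57-fold and OTX2 at least 2.78-fold. Of 11 anterior forebrain patterning genes, 6 fell and 0 rose (adjusted p = 0.0519), a list that passed without GnRH-EC 21 replicate 1 (0.042) or 2 (0.0294), or without GnRH-EC 35 replicate 1 (0.0351), with a range of 0.0161 to 0.18 over all alternatives. SPRY4 and ETV5 fell 2.63-fold and 2.34-fold, with 5 of 19 FGF feedback genes risen and 9 fallen (adjusted p = 0.672). ALPL, an alkaline phosphatase of stem cells, fell by 2.91 ± 0.19 log2. The glucose transporter gene SLC2A1 fell 4.36-fold.

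The cell cycle list moved down in GnRH-EC 35 against GnRH-EC 21, with 19 of 29 genes fallen and 2 risen, or 21 and 2 when adjusted over the list alone (camera adjusted p = 0.00209, or 0.179 with an estimated correlation). CDC20 fell by 1.56 ± 0.21 log2 and CCNE1 2.72-fold, while CENPF and TOP2A rose 3.91-fold and 2.85-fold. Cholesterol synthesis genes moved up, 8 of 12 with 1 falling, among them SC5D (4.82-fold), IDI1 (3.13-fold) and MSMO1 (2.54-fold). The cholesterol synthesis list had an adjusted p of 0.0285, or 0.179 with an estimated correlation, and did not pass without GnRH-EC 21 replicate 3 (0.117) or with median centring (0.119), and ranged from 0.000391 to 0.179 over all alternatives. MKLN1 rose 10.2-fold and the noncoding transcript COPG2IT1 at least 8.42-fold. CCDC71 fell at least 6.40-fold. RNA28SN5 (−4.63 ± 0.48) and the pseudogene ANXA2P1 (−2.78 ± 0.17) also fell, and both are uncertain because near-identical copies share their probes.

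In all, 2513 genes rose and 3173 fell between GnRH-EC 21 and GnRH-EC 35, of which 1285 and 723 changed at least 2-fold. With array weights 3361 passed, and with GnRH-EC 21 replicate 3 as the only array of its stage 2481. With only the arrays compared in the fit, 3826 passed. The share that rose was 44.2%, against 53.8% with cyclic loess and 37.2% with median centring. Of 33 lists, 2 passed. With camera's estimated correlation 0 held, and 5 had an unadjusted p under 0.05.

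The hormone that names the cells, and its receptors and regulators, were followed through every stage. GNRH1, the gene of GnRH, was detected on all 12 arrays. It rose 1.76-fold from ESC to NPC (0.82 ± 0.18 log2; limma adjusted p = 0.00116). In GNRH1, GnRH-EC 21 against NPC gave −0.40 ± 0.18 log2 (adjusted p = 0.0779) and GnRH-EC 35 against NPC gave −0.35 ± 0.18 log2 (adjusted p = 0.21), neither of which passed. The 95% intervals of these ratios reached 0.982-fold and 1.02-fold at their upper ends. The 21-day difference passed as a fall with cyclic loess (adjusted p = 0.0362), without GnRH-EC 21 replicate 3 (0.0291) and with the trend on gene length removed (0.0118), and its adjusted p ranged from 0.0118 to 0.6. Across the alternatives its log2 difference from NPC lay between −0.64 and −0.21 at 21 days and between −0.48 and −0.18 at 35 days. The difference in GNRH1 between 21 and 35 days did not pass either (0.05 ± 0.18; adjusted p = 0.841).

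KISS1R, the receptor through which kisspeptin acts on GnRH neurons, was detected on 7 arrays. In KISS1R, NPC against ESC gave a rise of 0.84 ± 0.27 log2 (adjusted p = 0.0153), which did not hold without ESC replicate 2 (0.0584) or NPC replicate 3 (0.0976) and ranged from 0.000315 to 0.0976 over all alternatives. At 35 days KISS1R was detected on 0 arrays and had fallen at least 1.75-fold from NPC (adjusted p = 0.00333). In KISS1R, GnRH-EC 35 against GnRH-EC 21 gave a fall of at least 1.38-fold (adjusted p = 0.01), a call lost without GnRH-EC 21 replicate 1 (0.0529) and with a range of 0.00234 to 0.084. FGFR1, a receptor for FGF8, rose at least 1.74-fold from NPC to 21 days (adjusted p = 0.00457) and fell at least 1.71-fold from 21 to 35 days (adjusted p = 0.00222). Both FGFR1 calls rest on 1 probe, detected on 5 arrays, and a second FGFR1 probe was detected on 0. On the 3 GnRH-EC 21 arrays the probe used read 6.34, 6.10 and 5.03 log2. With only the last of these, FGFR1, GnRH-EC 21 against NPC, did not pass (adjusted p = 0.415, the highest of a range from 9.58e-06). TAC3, the neurokinin B gene, fell at least 1.88-fold from ESC to NPC. It was detected on 1 NPC array and on 0 GnRH-EC arrays, so that no later change was measurable, although the difference between NPC and 21 days passed (adjusted p = 0.0175) and was lost under 9 of 21 alternatives. KISS1 and TACR3 were detected on 1 array each, and FGF8, NHLH2, ISL1 and DLX5 on 0, so that no change in them was measurable. Of 29 measured genes in which variants cause hypogonadotropic hypogonadism, 15 rose and 9 fell from ESC to NPC (adjusted p = 0.544), 7 rose and 10 fell from NPC to 21 days (0.389), and 2 rose and 2 fell from NPC to 35 days (0.926). Among 11 transcription factors that act on the GNRH1 promoter, the counts were 6 risen and 4 fallen (0.379), 4 and 1 (0.395), and 2 and 3 (0.926).

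The differences between stages followed gene length to different degrees. In the shortest 20% of genes by genomic length the median difference between GnRH-EC 21 and NPC was 0.27 log2, and in the longest 20% it was −0.14 (rank correlation −0.235 across 11907 genes, which are not independent replicates). Between GnRH-EC 35 and NPC the same medians were −0.04 and 0.02. They were −0.07 and 0.24 between NPC and ESC (rank correlation 0.12) and −0.32 and 0.14 between GnRH-EC 35 and GnRH-EC 21 (0.265). Replicate 1 of GnRH-EC 21 ran from 0.48 in the shortest 20% to −0.36 in the longest, and replicate 3 from 0.12 to 0.00. In the longest 20% the ESC arrays lay between −0.29 and −0.21. With the length trend removed, 84.9% of the genes called between GnRH-EC 21 and NPC were still called in the same direction.

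**Figure D3:**
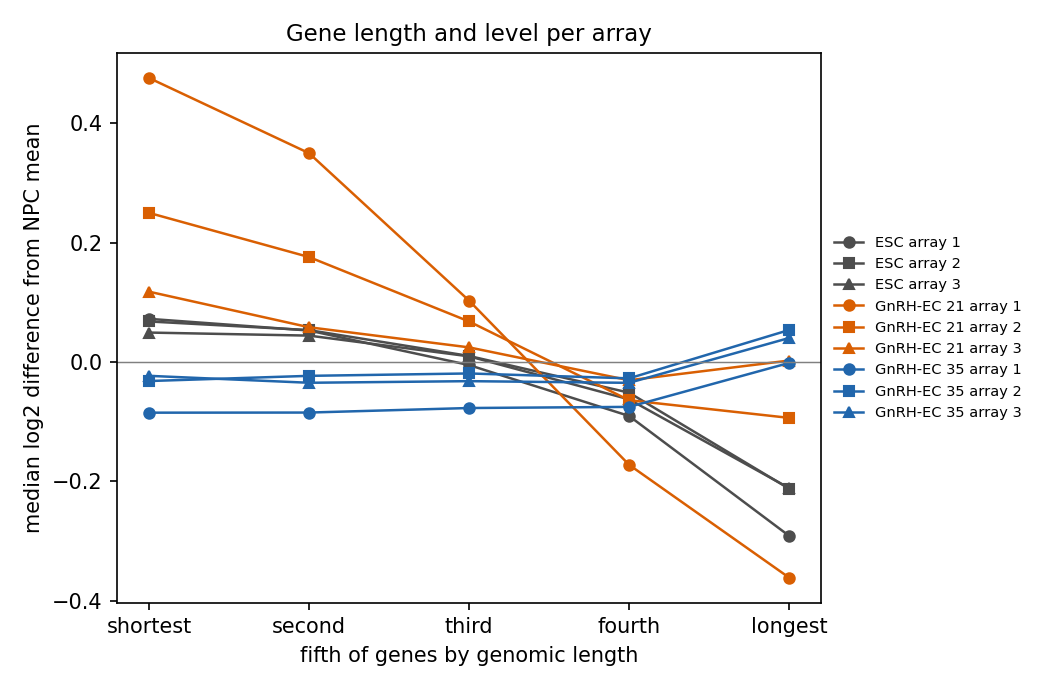
Median log2 difference from the NPC mean for the genes in 5 classes of equal size ordered by genomic length, with 1 line per ESC, GnRH-EC 21 or GnRH-EC 35 array. Replicate 1 of GnRH-EC 21 had the steepest line, from 0.48 in the shortest class to −0.36 in the longest, and the GnRH-EC 35 arrays stayed within 0.09 of 0.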

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

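The limma and camera tests between the days, the pan-neuronal test of replicate 3 and the splits of the arrays were planned beforehand. The other tests in this part were chosen after the result was seen. The day 35 and day 21 arrays were set against the same NPC arrays, and each result below was picked out because the change differed between the days by a limma or camera test of that difference. Of 1060 genes that passed the threshold at both days, 915 moved in the same direction and 145 in opposite directions. The NPC arrays are shared by both comparisons, so no chance level is given for these counts, and for the 145 a difference between the days follows almost of itself. Of the 145, 83 rose at 21 days and fell at 35, and 62 did the reverse. APOE was among the former and ST18 among the latter. The cell cycle list was lower at day 35 than at day 21 (adjusted p = 0.00209) and the cholesterol synthesis list was higher (adjusted p = 0.0285). Both calls were lost with an estimated correlation (adjusted p = 0.179 each), and the cholesterol call also without GnRH-EC 21 replicate 3 and with median centring. The fitted difference, day 35 minus day 21, was −0.939 log2 for KISS1R, −1.18 for FGFR1 and 0.902 for SOX2. For SOX2 it ranged from 0.551 to 1.22 over the alternatives. A second SOX2 probe overlapped between the days, at 9.74 to 10.76 log2 at 21 days and 10.64 to 11.26 at 35 days. KISS1R and FGFR1 were not detected at 35 days, so their values show only that they fell at least 1.38-fold and at least 1.71-fold.

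The 21-day arrays differed from each other, with long genes lowest on replicate 1. Array brightness as the cause was argued against, since the mean intensity of replicate 1 was 0.974 times that of replicate 3. A replicate 3 less far along the same differentiation stays open: its mean pan-neuronal rise over NPC was 1.30 times that of replicate 1 (95% bootstrap interval over genes 1.01 to 1.94, and 1.24 with the length trend removed), but this sets 1 array against 1 array and 1 gene list, and over all genes replicate 3 correlated with the NPC mean at 0.953 and replicate 1 at 0.878. Replicate 3 was also closer to the GnRH-EC 35 arrays, at 0.936 to 0.954, than replicate 1 was, at 0.855 to 0.871. The difference of replicate 1 and replicate 3 had a rank correlation of −0.349 with genomic length, against 0.107 at most for a pair of another group. This value restates the pattern, so RNA or labelling quality that changes with gene length and a state of the 21-day cultures that lowers long genes cannot be told apart.

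A smooth trend on genomic length alone did not account for most genes called between NPC and 21 days. After its removal 84.9% of the called genes were still called in the same direction. An effect of RNA or labelling quality that does not follow genomic length would survive this removal and was not tested. What the trend itself reflects stays open.

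The mean of GNRH1 was not higher on the GnRH-EC arrays than in NPC. A probe at the background was argued against, since the lowest stage mean lay 1.07 log2 above the lowest detected signal. Removal of the length trend moved the 21-day difference of GNRH1 from −0.405 to −0.642 (95% interval −1.04 to −0.248). The trend had therefore raised GNRH1 on the 21-day arrays relative to NPC. It could not have hidden a rise in this gene, so its removal was no test of one. Dilution of GNRH1-expressing cells by other cells, and a probe with a poor response, stay open and were not tested.

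The 6 arrays of each comparison make 10 splits into 3 and 3, too few for a share under 0.05. The real split alone, 1 of 10, gave the real count in each comparison, which was 6294 for NPC against ESC, 5142 and 1927 for 21 and 35 days against NPC, and 5686 between the days, with 0 genes in the highest other split. For any difference among the 4 stages, 1 of 100 groupings, the real one, reached 9585 genes and the highest other reached 5130. This argues against a random assignment of arrays to stages. It cannot exclude chance differences between single cultures, since the replicates of a stage may be technical.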

How the results depend on the processing

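Array weights, removal of the length trend and the use of the 21-day array 3 alone (without 21-day replicates 1 and 2, the remaining array being assumed to vary like the other groups) were chosen after the data were seen. Of the values of named genes under the alternatives, 9619 stayed on the same side of the threshold, 566 no longer passed, 19 newly passed and 2 reversed. A change of direction was counted as a reversal only where the gene passed in the main analysis or under the alternative. Values that passed in neither were counted as staying on their side whatever their direction. Of those of the called lists, 412 kept their call and 64 lost it.

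A 2-fold minimum lowers every count by construction, to 3073 for NPC against ESC, 1830 for GnRH-EC 21 against NPC, 790 for GnRH-EC 35 against NPC, 2008 for GnRH-EC 35 against GnRH-EC 21 and 5053 for any difference among the 4 stages. The share that rose became 32.7% in the second and 64% in the fourth. Array weights gave 3084, 4337 and 3361 for the last 3 comparisons, with a limma warning that the convergence tolerance was not achievable. With only the 21-day array 3, 2121 genes passed against NPC and 2481 between the days, in a fit with fewer arrays. With only the arrays compared, 3035 passed in GnRH-EC 35 against NPC. Under only the 21-day array 3, SPARCL1, GnRH-EC 21 against NPC, reversed to 0.0347 and GJA1, GnRH-EC 35 against GnRH-EC 21, to −0.0137. The cause was not tested for array weights, for only the arrays compared or for these reversals.

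An estimated correlation left 4 lists called in NPC against ESC, 0 at 21 days, 9 at 35 days and 0 between the days. Median centring left 3 at 21 days and 1 between the days. Between the days, cyclic loess, no detection filter and removal of the length trend each gave 4, and only the 21-day array 3 gave 7. The cause was not tested.

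Leaving out each array in turn gave 5528 to 5655 genes for NPC against ESC, 3897 to 6604 at 21 days, 1349 to 1599 at 35 days, 4451 to 6998 between the days and 9027 to 10264 for any difference. The highest counts at 21 days and between the days came without GnRH-EC 21 replicate 3. Lists ranged from 13 to 13, 3 to 8, 13 to 15 and 1 to 4.

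With the replicate number as a replicate block, 6282, 5099, 1879 and 5662 genes passed in the 4 comparisons and 9536 for any difference. As a check of pairing, 0, 6, 1 and 0 of the 6 arrays in the 4 comparisons were closest to the array of their own number. The 6 had correlations of 0.0791 to 0.178, a hint only, and the labels do not say that numbers pair samples. Under that block the anterior forebrain and GABA lists of GnRH-EC 21 against NPC had an adjusted p of 0.0516. A slide block was not run, since slides were not given. Signal over background limits the genes near the detection floor, among them KISS1R and FGFR1, whose folds are lower bounds.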

Other observations

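The families and tests in this part were chosen after their values were seen, and each count was checked under cyclic loess, median centring and removal of the length trend. Of the 4 nuclear factor I genes, 1 had risen at 21 days against NPC, or 2 with median centring and with the length trend removed, and 3 of 4 rose at 35 days against NPC and against 21 days, in the main analysis and under those 3 alternatives. NFIA rose at least 6.89-fold from NPC to 35 days and NFIB by 3.09 ± 0.24 log2 (limma adjusted p = 3.79e-07), while NFIC did not pass (adjusted p = 0.858). Of 8 S100 genes, 5 fell at 21 days against NPC, or 6 with the length trend removed, and 6 fell at 35 days under each of the 4 settings. S100A6 fell at least 3.01-fold at 21 days and at least 3.28-fold at 35 days. No test was made of any family as a whole. Of the 4 BMP-responsive ID genes, 3 had risen and 1 had fallen at 21 days against NPC, or 0 had fallen with median centring. At 35 days 4 had risen against NPC, or 3 under cyclic loess and median centring.

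Of 6 metallothionein genes, 5 fell from ESC to NPC and 1 rose, or 0 rose with median centring, and from NPC to 35 days 5 fell, or 4 with cyclic loess and median centring. Against NPC 2 had fallen at 21 days, with a family median of 0.00 log2, and 4 fell between 21 and 35 days, or 3 with cyclic loess and with the length trend removed. MT1X fell by 3.48 ± 0.20 and then by 1.93 ± 0.20 log2, although near-identical copies make single members uncertain. Of 4 Iroquois genes, 3 rose from ESC to NPC, or 4 with cyclic loess and with the length trend removed, led by IRX3 at 5.18 ± 0.16 log2. Of 10 hosts of microRNAs, 6 rose and 0 fell between 21 and 35 days under each of the 4 settings, among them MIR100HG at 2.17 ± 0.21 log2. Of 26 replication-dependent histone genes, many with near-identical copies, 14 rose and 0 fell at 21 days against NPC (11 to 16 rose under the 3 alternatives). Between the days 13 fell and 0 rose, or 7 and 1 with the length trend removed and 10 and 0 with cyclic loess. Most messages of these genes lack a poly-A tail, and the ribosomal RNA probe of RNA28SN5 moved with them, by 3.79 log2 at 21 days and by −4.63 log2 between the days. The cause of these shared changes was not tested. Of 345 zinc finger genes of the ZNF series 63 rose and 118 fell at 21 days against NPC (95 to 122 fell under the 3 alternatives).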
